A study of Homo sapiens with 4 samples.

How the data were processed

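RNA-seq was performed on 2 samples labelled HEK293 and 2 labelled Synph-293. HEK293 is a widely used line derived from human embryonic kidney, and Synph-293 is the same line made to overexpress synphilin-1, a cytoplasmic protein encoded by SNCAIP. Per the labels' protocols, cells were grown untreated in serum-containing medium, poly(A) RNA was used, stranded mRNA libraries were made by random hexamer priming and PCR, and they were sequenced as read pairs on an Illumina NovaSeq instrument. The same protocols name a total RNA library kit for the isolation of the RNA and an mRNA kit for the libraries, so that the selection of poly(A) RNA is as labelled and not certain. The labels do not say whether the 2 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. They also do not say whether Synph-293 was a single clone or a pool.

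The deposited table held, for 60676 annotated genes and each of the 4 samples, a read count, an RPKM and a TPM value. The deposited read counts were treated as estimated counts already rounded by the authors, because between 43 and 63 genes per sample had a count of 0 and a TPM above 0. The RPKM and TPM values were normalised by the authors for gene length and for the size of the library, and the deposited RPKM values were not used. The submitters' processing notes named cutadapt 2.8, STAR 2.7.1a, RSEM 1.3.1, featureCounts 2.0.0, HTSeq 0.11.2 and Cufflinks 2.2.1 and the build GRCh38.p13. They did not give the role or order of these tools, and the strand setting of the counting is not given in the sources used here. Because that setting is unknown, reads of a gene and of an overlapping or antisense gene may have been counted together. Of SNCAIP and the 24 genes with the largest changes, 16 overlap another gene of the deposited annotation, 15 of them a gene on the opposite strand. Near-identical copies can share reads in the same way, which concerns the clustered protocadherins, the histone genes, HSPA1A with HSPA1B, and ribosomal protein genes with processed pseudogenes.

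Library totals were 16998732 and 13284417 counts in HEK293 replicates 1 and 2 and 16471847 and 16634633 in Synph-293 replicates 1 and 2. Limits for genes at 0 were set at 3 counts per library, which corresponded to between 0.178 and 0.225 CPM. Where a group was at 0 in both libraries, a fold is a lower bound against that limit. Where a group held 1 to 3 counts in all, the ratio of the groups is given with an exact conditional binomial 95% interval. Bounds and intervals cover counting error only, since the reads carried no molecular identifiers. The replicates of a group were not the same library, as their counts differed by more than sampling noise, with a chi-square per degree of freedom of 27.1 in HEK293 and 19.1 in Synph-293.

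Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16421 genes, and libraries were scaled by TMM. Synph-293 was compared with HEK293 by edgeR's quasi-likelihood test with group as the only term, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The biological coefficient of variation was 13.0%.

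Before the data were examined, 36 gene lists holding 909 symbols were fixed, among them markers of cell types that a culture could hold. Of these, 907 matched the symbols of the deposited table and 2 matched by current symbols. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 36 lists, then with an estimated correlation and with fry. The numbers of members past the threshold are given over all genes tested and adjusted over the list alone. Only members that passed the filter were tested, such as 16 of 25 listed NF-kB genes and 9 of 20 catecholaminergic markers. Likewise 12 of 24 kidney and adrenal, 10 of 24 blood and immune and 6 of 15 endothelial genes were tested. The genes to be named were also fixed by a rule. It took SNCAIP, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group, non-overlapping replicates and a symbol that is not a clone name, LOC number, antisense, pseudogene or readthrough symbol; some of the genes so chosen are not reported here. It further took up to 4 members past the threshold from each list, those with the largest change. From these, examples that passed without each library in turn were preferred in the text, a choice made after the values were seen, and any other member named was also chosen after its value was seen.

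On data simulated from the means and library sizes of these samples, with 631 of 16421 genes changed, 100 of them by 2-fold and 100 by 4-fold, the test recovered 72.0% of the 2-fold and 99.0% of the 4-fold changes, and 8.5% of its calls were unchanged genes. Alternatives were other scalings, filters and thresholds, the DESeq2 1.42.0 Wald test, limma on the log2 of the deposited TPM plus 1 or plus 0.1, glmTreat against a 1.5-fold change, the replicate number as a block, SNCAIP left out of the scaling, and each library left out in turn. With 1 library left in a group, that library was assumed to vary like the other group. Coordinates are those of the deposited table. GC content and transcript length came from a GENCODE transcript set for the same build.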

Results

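Gene expression was measured by RNA-seq in 2 HEK293 libraries and 2 Synph-293 libraries, to compare HEK293 cells with HEK293 cells that overexpress synphilin-1. Library totals lay between 13284417 and 16998732 counts, and between 22087 and 23854 genes had a count above 0. Across genes, log2 CPM correlated at 0.986 between the HEK293 libraries, at 0.989 between the Synph-293 libraries and at 0.947 to 0.953 between libraries of different groups (genes are not independent replicates). The share of counts from mitochondrially encoded genes varied within both groups, from 7.76% to 10.6% in HEK293 and from 7.28% to 10.9% in Synph-293.

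SNCAIP (ENSG00000064692, chromosome 5, 122311354 to 122464219, plus strand, GRCh38), which encodes synphilin-1, was the overexpressed gene and separated the groups. It had 17 and 16 counts in the HEK293 libraries and 22911 and 24834 in the Synph-293 libraries, or 1.10 ± 0.135 CPM against 1445 ± 112 CPM (SD, n = 2 each). Its log2 fold change was 10.36 ± 0.29 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.18e-08). SNCAIP made up 0.139% and 0.149% of the counts of the Synph-293 libraries, and leaving it out of the scaling changed no call. The gene-level counts hold no information on which part of the transcript was introduced.

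Beyond SNCAIP, genes of neuronal identity, synaptic adhesion, WNT and BMP signalling and histones were higher in Synph-293, and genes of cholesterol synthesis, ER chaperones, lysosomes and antioxidant defence were lower, as gene lists tested with a preset correlation between genes (limma camera). With an estimated correlation 0 of 36 lists passed, and only the cholesterol, neuronal and histone lists passed whichever library was left out. The WNT receptor component LGR5 rose from 7.02 ± 0.391 to 192 ± 25.5 CPM, the ephrin receptor EPHA7 from 0.164 ± 0.0199 to 37.4 ± 4.54 CPM, and the neurofilament gene NEFL from 37.4 ± 4.14 to 169 ± 11.9 CPM (SD, n = 2 each). DEPP1, a FOXO-regulated gene, fell from 335 ± 7.15 to 14.3 ± 0.766 CPM, and PARP14, an ADP-ribosyltransferase, from 48.2 ± 1.26 to 3.81 ± 0.25 CPM. In all, 1648 genes were higher and 1081 lower in Synph-293, or 16.6% of the 16421 genes tested (edgeR, adjusted p under 0.05). With a change of at least 2-fold as well, 1067 were higher and 338 lower. Protein-coding genes made up 1428 of the higher and 967 of the lower genes. Both counts rose when either HEK293 library was left out and fell when either Synph-293 library was left out, the lower count more. Such fits take the spread from the group that keeps both libraries, so these changes are not traced to single libraries. Neighbouring genes shifted together along parts of the chromosomes, and with the median log2 fold change of the 30 nearest genes removed, a setting chosen after seeing the data, 1239 genes were higher and 565 lower.

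Several of the largest rises were of genes without any count in HEK293. The long noncoding RNA LINC00305 went from 0 to 48.5 ± 2.37 CPM, at least 241-fold higher, and the zinc finger gene ZNF334 from 0 to 21.9 ± 0.829 CPM, at least 109-fold higher. The ubiquitin ligase gene DTX3 was at least 77.1-fold, the cadherin CDH4 at least 73.4-fold, the cysteine dioxygenase CDO1 at least 27.3-fold and the zinc finger gene ZNF626 at least 26.9-fold higher. A few counts in HEK293 were found for TCEAL7 (ratio 448, interval 80.0 to 17719), the glycosyltransferase GALNT14 (341, 60.8 to 13497), the DNA sensor IFI16 (326, 58.2 to 12919), the WNT receptor FZD10 (235, 41.8 to 9310) and KRBOX1 (185, 32.9 to 7362). EPHA7, the remaining gene of the 12 largest rises among genes eligible to be named, had a log2 fold change of 7.75 ± 0.31. Over these 12 genes, the highest adjusted p was 4.56e-05 (CDO1, edgeR). All 12 were higher in 2 of 2 Synph-293 libraries, which the rule for naming them required.

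Among the largest falls, the neural transcription factor gene MYT1L went from 17.9 ± 4.07 to 0.0605 ± 0.00125 CPM, a ratio of 302 (interval 83.2 to 2500). The glutamine transporter SLC38A5 had a log2 fold change of -5.84 ± 0.29, DEPP1 of -4.55 ± 0.19, FAM71F2 of -4.32 ± 0.27 and the endogenous retroviral gene ERVMER34-1 of -4.15 ± 0.33. The proteoglycan gene BGN had -4.04 ± 0.45, with low counts in Synph-293, and its log2 fold change was -5.64 without Synph-293 replicate 1 and -3.31 without Synph-293 replicate 2. PARP14 had a log2 fold change of -3.66 ± 0.18, the retinol dehydrogenase RDH10 of -3.05 ± 0.18, the mitochondrial folate enzyme ALDH1L2 of -2.78 ± 0.17 and the syntaxin-binding gene STXBP2 of -2.65 ± 0.27. The thrombospondin THBS2 had -2.61 ± 0.36, but did not pass in limma on log2 TPM (adjusted p up to 0.0804, 1.97e-17 to 0.0804 over its alternatives). The highest adjusted p of these falls was 0.000601 (THBS2, edgeR).

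**Figure D1:**
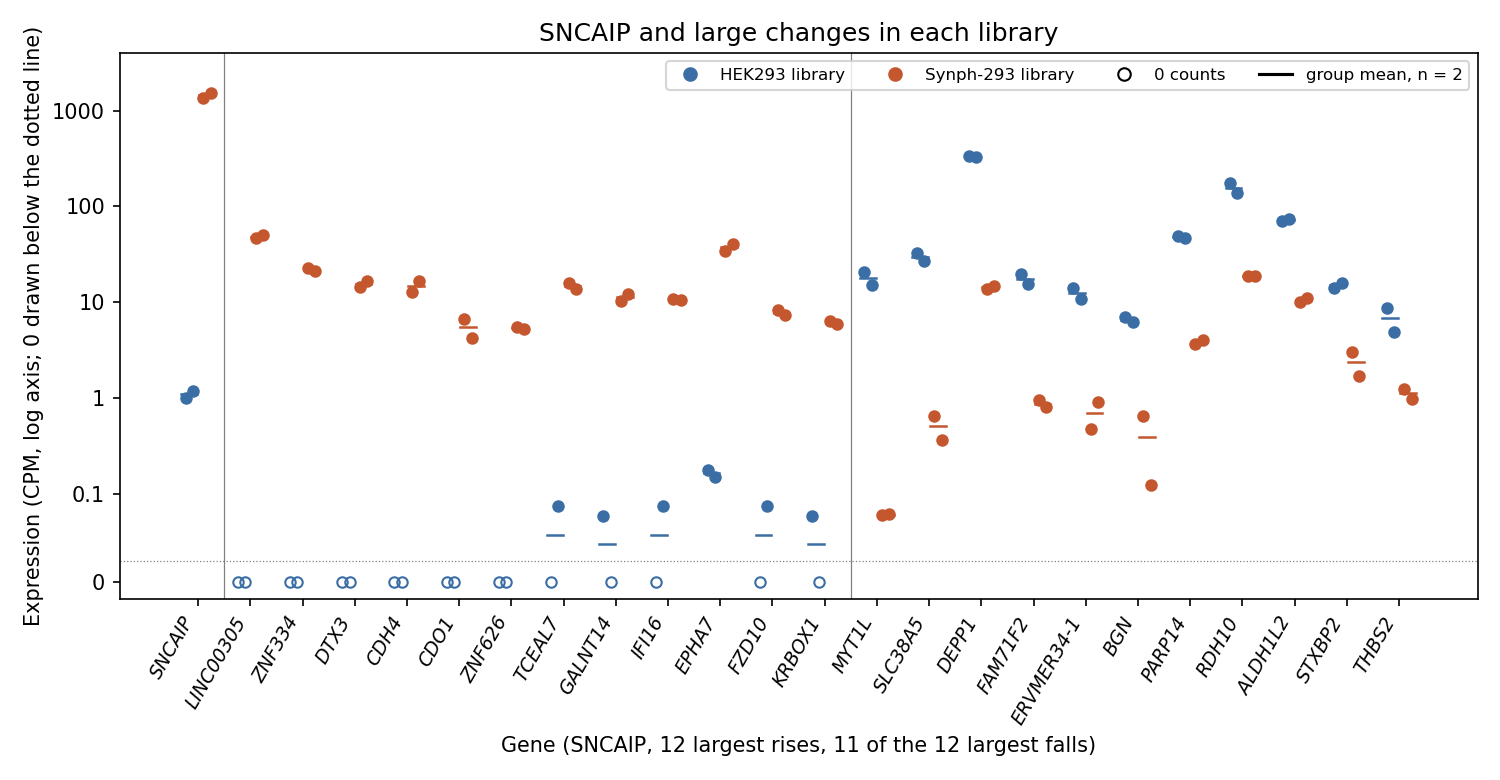
Expression in CPM on a log axis in each of the 4 libraries for SNCAIP, the 12 largest rises and 11 of the 12 largest falls among the genes eligible to be named, with filled points for libraries, lines for group means (n = 2) and open points for 0 counts. SNCAIP lies near 1.10 CPM in HEK293 and 1445 CPM in Synph-293, and the replicates of a group lie closer to each other than to the other group for every gene drawn. Genes other than SNCAIP were eligible only if the libraries of the groups did not overlap.

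Genes for synphilin-1 partners and for Parkinson disease did not move as a group. Of 30 members tested, 2 were higher (SNCB and USP9X) and 3 lower (RNF19A and DNAJC6 among them), as also when adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.0878), although it did without HEK293 replicate 1 (0.0490) and without a filter (0.0409; 0.0409 to 0.345 over the alternatives). DNAJC6 was not called without Synph-293 replicate 1 or 2 (edgeR adjusted p = 0.146 and 0.247; 0.00057 to 0.247 over the left-out libraries). The ubiquitin ligases SIAH1 and SIAH2 had log2 fold changes of -0.19 ± 0.20 and -0.14 ± 0.18, and the kinase PINK1 had -0.12 ± 0.16, with none of the 3 past the threshold. Beta-synuclein SNCB went from 0.471 ± 0.499 to 2.21 ± 0.168 CPM, with a log2 fold change of 1.41 without HEK293 replicate 1 and 4.13 without HEK293 replicate 2. The ubiquitin ligase RNF19A fell by 0.84 ± 0.17 on the log2 scale and was not called without Synph-293 replicate 1 (edgeR adjusted p = 0.111, 1.37e-09 to 0.637 over its alternatives). Its log2 fold change was -0.16 with the median of its neighbours removed (adjusted p = 0.637). The deubiquitinase USP9X rose by 0.67 ± 0.17 and was not called without Synph-293 replicate 1 or 2 (edgeR adjusted p = 0.179 and 0.197, 1.34e-06 to 0.375 over its alternatives).

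Of the 36 lists, 9 shifted upward and 5 downward with the preset correlation (limma camera, adjusted p under 0.05), and 0 passed with an estimated correlation, where 2 residual degrees of freedom were left. Without the adjustment, the smallest p with an estimated correlation were 0.0509 for the neuronal and 0.0551 for the histone list. By fry, which asks whether the genes of a list move one way, 7 lists passed: the neuronal list (adjusted p = 4e-04), and, each at an adjusted p of 0.0411, the epithelial, WNT, histone, catecholaminergic, kidney and adrenal, and HOX lists. The 5 lists that camera called downward did not pass fry (adjusted p from 0.153 for the cholesterol to 0.423 for the lysosomal list). The median and the camera direction differed in sign for 3 lists that did not pass: glycolysis (median 0.0037, downward), mesenchymal (-0.0019, upward) and blood and immune (-0.11, upward), and the Notch list had a median of -0.05 and a mean of 0.11. The cholesterol, neuronal and histone lists passed camera in all 14 alternatives that kept the preset correlation.

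Cholesterol synthesis genes were lower in Synph-293. Of 23 tested, 0 were higher and 11 lower, or 1 and 15 when adjusted over the list alone, and the median log2 fold change was -0.56 (camera adjusted p = 0.000619; adjusted p = 0.705 with an estimated correlation). INSIG1, a sterol sensor, fell from 64.7 ± 17.2 to 30.4 ± 2.72 CPM. The squalene epoxidase SQLE fell from 195 ± 62.0 to 109 ± 18.4 CPM and the isomerase IDI1 from 44.0 ± 1.99 to 25.1 ± 3.33 CPM. SQLE was not called without Synph-293 replicate 1 (edgeR adjusted p = 0.198, 3.29e-10 to 0.198 over its alternatives), nor IDI1 without Synph-293 replicate 2 (0.120, 3.93e-09 to 0.120). HMGCS1 had a log2 fold change of -0.0014 ± 0.155 and was not past the threshold. Of fatty acid and lipid storage genes, 1 of 22 was higher and 2 were lower, as also when adjusted over the list alone (camera adjusted p = 0.0878; 0.0290 with the median of neighbouring genes removed, 0.0290 to 0.178 over the alternatives). The desaturase SCD was at 778 ± 161 CPM in HEK293 and 389 ± 50.4 CPM in Synph-293. The call of SCD was lost without Synph-293 replicate 1 (edgeR adjusted p = 0.0965, 4.52e-13 to 0.0965 over its alternatives).

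ER chaperone genes and lysosomal genes were also lower, and in both lists HEK293 replicate 1 stood apart. For ER chaperones, 0 of 21 were higher and 6 lower, or 0 and 8 adjusted over the list alone, with a median log2 fold change of -0.32 (camera adjusted p = 0.00303; adjusted p = 0.804 with an estimated correlation). The disulfide isomerase PDIA4 fell from 676 ± 195 to 266 ± 40 CPM, HYOU1 from 518 ± 116 to 217 ± 36.7 CPM and HERPUD1 from 80.7 ± 13.7 to 38.3 ± 1.35 CPM, whereas the main ER chaperone HSPA5 had a log2 fold change of -0.23 ± 0.21. With the median of neighbouring genes removed, the log2 fold change of PDIA4 went from -1.347 to -1.014. That of HYOU1 went from -1.253 to -0.7201 and that of HERPUD1 from -1.075 to -0.9407. The mean log2 level of the list, relative to the mean of the 4 libraries, was 0.43 in HEK293 replicate 1, 0.01 in HEK293 replicate 2, and -0.32 and -0.12 in Synph-293. Without HEK293 replicate 1 the median was -0.05 and the call was lost (camera adjusted p = 0.0662, 4.14e-05 to 0.0662 over the alternatives). Of 27 lysosomal genes, 0 were higher and 6 lower, or 1 and 9 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.0228; adjusted p = 0.804 with an estimated correlation). PSAP, the precursor of the saposins, fell from 748 ± 195 to 337 ± 31.6 CPM, and the sialidase NEU1 from 122 ± 21.6 to 59.5 ± 3.54 CPM. The lysosomal call was lost without HEK293 replicate 1 (camera adjusted p = 0.179) and without Synph-293 replicate 1 (0.0935; 0.000295 to 0.179 over the alternatives).

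Antioxidant genes were also lower, and a list of respiratory genes shifted downward with few members called. Of 25 NRF2 targets, 0 were higher and 7 lower, or 1 and 7 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.0228; adjusted p = 0.804 with an estimated correlation). The cystine transporter SLC7A11 fell from 35.3 ± 12.1 to 13.4 ± 2.29 CPM, and GCLM, a subunit of the enzyme that starts glutathione synthesis, from 28.8 ± 0.939 to 14.6 ± 2.52 CPM. The NRF2 call was lost without HEK293 replicate 2 (camera adjusted p = 0.214) and without Synph-293 replicate 2 (0.0920; 0.00272 to 0.214 over the alternatives). Of 35 nuclear oxidative phosphorylation genes, SDHD and COX6C were lower and 0 higher, with 1 lower adjusted over the list alone and a median of -0.17 (camera adjusted p = 0.0462; adjusted p = 0.804 with an estimated correlation). That list passed in 10 of 14 alternatives and was lost with a filter of 1 CPM (camera adjusted p = 0.0578), without HEK293 replicate 2 (0.217) and without Synph-293 replicate 2 (0.370; 0.00723 to 0.370 over the alternatives). SDHD was not called without Synph-293 replicate 2 (edgeR adjusted p = 0.147, 2.67e-12 to 0.197 over its alternatives). COX6C was called without HEK293 replicate 2 but not without any other library (0.120 to 0.310; 8.69e-06 to 0.814 over its alternatives), and its log2 fold change of -0.59 became 0.0916 with the median of its neighbours removed. None of the 13 mitochondrially encoded mRNAs passed (edgeR; 0 also adjusted over the list alone; camera adjusted p = 0.579). The list passed downward only without Synph-293 replicate 2 (0.0218; 0.0218 to 0.833 over the alternatives).

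As a list, neuronal genes were higher in Synph-293, over the 18 of 30 listed members that could be tested. Outside the list, the neural transcription factor gene MYT1L was lower in Synph-293 by a ratio of 302 (interval 83.2 to 2500). Of 18 tested, 10 were higher and 2 lower, or 11 and 2 adjusted over the list alone, with a median log2 fold change of 0.83 (camera adjusted p = 0.000743; adjusted p = 0.705 with an estimated correlation). NEFL rose by 2.17 ± 0.17, the synaptic vesicle gene SYP rose from 2.24 ± 0.0994 to 7.29 ± 0.0632 CPM, and the RNA-binding protein gene ELAVL2 went from 0 to 1.85 ± 0.252 CPM, at least 9.18-fold higher. The dendritic gene MAP2 and the secretogranin SCG2 were the lower members, with log2 fold changes of -0.82 ± 0.17 and -1.64 ± 0.34, and MAP2 was not called without Synph-293 replicate 2 (edgeR adjusted p = 0.0522, 3.28e-05 to 0.0522 over the left-out libraries). Synaptic adhesion and axon guidance genes moved the same way, with 11 of 31 higher and 1 lower, or 12 and 3 adjusted over the list alone, and a median of 0.37 (camera adjusted p = 0.000619; adjusted p = 0.804 with an estimated correlation). The neurexin NRXN3 went from 0 to 1.94 ± 0.553 CPM, at least 9.64-fold higher, and the guidance cue SLIT3 from 1.08 ± 0.15 to 8.57 ± 1.33 CPM. This call was lost without HEK293 replicate 2 (camera adjusted p = 0.0583, 2.26e-05 to 0.0583 over the alternatives). Of 26 calcium handling and ion channel genes, 6 were higher and 1 lower, or 8 and 1 adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.0462; adjusted p = 0.804 with an estimated correlation). The calcium channel subunit CACNA1C rose from 3.45 ± 0.322 to 21.0 ± 0.862 CPM. The channel list passed in 8 of 14 alternatives. It was lost with a filter of 1 CPM (camera adjusted p = 0.105), in limma on log2 TPM (0.112 and 0.0702), without HEK293 replicate 2 (0.345) and without Synph-293 replicate 2 (0.260, with a median of -0.07; 0.00723 to 0.345 over the alternatives). Of 9 catecholaminergic markers tested, from 20 listed, 4 were higher and 1 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0878). The dopamine transporter SLC6A3 was lower in Synph-293 by a ratio of 16.4 (interval 5.27 to 82.6).

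The WNT and the TGF-beta and BMP lists were higher as well, while the HOX and Notch lists did not pass in the main fit. Of 17 WNT targets, 6 were higher and 0 lower, or 7 and 0 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.0101; adjusted p = 0.705 with an estimated correlation). LGR5 rose by 4.77 ± 0.20, the WNT antagonist SFRP1 from 10.3 ± 1.54 to 45.7 ± 0.553 CPM and the cyclin CCND1 from 41.4 ± 7.13 to 131 ± 7.94 CPM. Of 22 TGF-beta and BMP targets, 8 were higher and 0 lower, or 10 and 2 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.0101; adjusted p = 0.705 with an estimated correlation). BMP2 rose from 1.56 ± 0.399 to 17.8 ± 0.495 CPM and TGFB1 from 32.6 ± 0.676 to 75.3 ± 3.91 CPM. Without HEK293 replicate 2, the WNT list (camera adjusted p = 0.0652, 0.00108 to 0.0652 over the alternatives) and the TGF-beta list (0.0583, 0.000317 to 0.0583) no longer passed. Of 32 HOX genes, 8 were higher and 1 lower, or 11 and 1 adjusted over the list alone, but the list did not pass (camera adjusted p = 0.175) except with the median of neighbouring genes removed (0.0109; 0.0109 to 0.370 over the alternatives). HOXB8 went from 2.86 ± 0.232 to 15.3 ± 1.43 CPM and HOXB6 from 10.0 ± 1.37 to 24.1 ± 1.51 CPM. Notch genes split, with 3 of 17 higher and 2 lower, as also adjusted over the list alone (camera adjusted p = 0.811). The Notch target HEY1 fell from 143 ± 0.767 to 34.2 ± 0.362 CPM. Its log2 fold change of -2.068 became -1.565 with the median of its neighbours removed. HES5, of the same list, rose with a log2 fold change of 3.855, or 3.787 with the median of its neighbours removed. The receptor NOTCH3 rose from 86.5 ± 25.3 to 155 ± 2.42 CPM. The call of NOTCH3 was lost in limma on log2 TPM and with the median of its neighbours removed, where its log2 fold change of 0.84 became 0.49 (adjusted p = 0.155, 1.28e-11 to 0.155 over its alternatives).

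Extracellular matrix and epithelial genes rose in small numbers. Of 21 matrix and fibroblast markers, 7 were higher and 0 lower, as also adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.0382; adjusted p = 0.804 with an estimated correlation). The collagens COL3A1 and COL5A2 rose from 6.88 ± 2.43 to 37.6 ± 0.177 CPM and from 21.1 ± 6.37 to 63.1 ± 9.04 CPM. Outside this list, the proteoglycan gene BGN and the thrombospondin THBS2 were among the largest falls, with log2 fold changes of -4.04 ± 0.45 and -2.61 ± 0.36. The matrix call was lost in limma on log2 TPM plus 1 (camera adjusted p = 0.0818) and plus 0.1 (0.105), without HEK293 replicate 2 (0.233) and without Synph-293 replicate 2 (0.104; 0.00272 to 0.233 over the alternatives). Of 18 epithelial markers, 4 were higher and 0 lower, as also adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.0495; adjusted p = 0.705 with an estimated correlation). The keratins KRT8 and KRT19 rose from 712 ± 76.1 to 1446 ± 143 CPM and from 76.9 ± 6.55 to 149 ± 12.2 CPM. The epithelial list passed in 8 of 14 alternatives and was lost without a filter (camera adjusted p = 0.102), without HEK293 replicate 1 (0.124), HEK293 replicate 2 (0.0736) and Synph-293 replicate 2 (0.191; 0.00517 to 0.191 over the alternatives). Of 19 mesenchymal transition genes, SNAI2 and FN1 were higher and 0 lower, as also adjusted over the list alone (camera adjusted p = 0.766). SNAI2 went from 0.403 ± 0.0662 to 3.24 ± 0.366 CPM, and FN1, from 71.0 ± 17.3 to 125 ± 24.7 CPM, was not called without Synph-293 replicate 2 (edgeR adjusted p = 0.204, 1.08e-10 to 0.204 over its alternatives). Of 12 kidney and adrenal lineage genes, 4 were higher and 1 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0744; 0.0109 with the median of neighbouring genes removed, 0.0109 to 0.154 over the alternatives). PAX2 was at 0.685 ± 0.121 CPM in HEK293 and 5.11 ± 0.194 CPM in Synph-293.

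Markers of blood and of endothelial cells did not pass as lists. Of 10 blood and immune markers tested, CORO1A and CD68 were higher and 0 lower, as also adjusted over the list alone (camera adjusted p = 0.796), and CORO1A had 5.58 ± 0.907 CPM in HEK293 and 10.2 ± 1.46 CPM in Synph-293. Each of these 2 calls was lost without 1 of the Synph-293 libraries. The log2 fold change of CORO1A was 0.858, or 0.7186 without Synph-293 replicate 1. That of CD68 was 0.7601, or 0.6453 without Synph-293 replicate 2. CORO1A also lost its call with the median of neighbouring genes removed (edgeR adjusted p = 0.0708), and CD68 with the replicate block (edgeR adjusted p = 0.0517). Of 6 endothelial markers, ERG was higher and EGFL7 lower, as also adjusted over the list alone (camera adjusted p = 0.573), and EGFL7 fell from 97.7 ± 31.0 to 39.0 ± 2.79 CPM.

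Replication-dependent histone genes showed the highest list median, over the 9 of 29 listed genes that could be tested. The filter can keep a gene for its counts in 1 group alone, so these 9 need not stand for the list. Of 9 tested, 6 were higher and 0 lower, or 7 and 0 adjusted over the list alone, with a median of 1.17 (camera adjusted p = 0.000323; adjusted p = 0.705 with an estimated correlation). H1-2 rose from 3.38 ± 0.0882 to 12.3 ± 2.61 CPM. H2BC12 had 0 and 5 counts in HEK293 and 223 and 171 in Synph-293, and its log2 fold change of 6.09 became 4.95 without HEK293 replicate 1 and 10.63 without HEK293 replicate 2. Most transcripts of these genes lack a poly(A) tail, so poly(A) selection, which the labels name but beside a total RNA kit, would measure a minor part of them. Cell cycle genes did not move with them, as CCNE1 was the only 1 of 30 higher and 0 were lower, also adjusted over the list alone (camera adjusted p = 0.374), and the proliferation marker MKI67 had a log2 fold change of -0.11 ± 0.20.

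Immediate early genes moved in both directions. Of 28 tested, 9 were higher and 5 lower, or 12 and 5 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.0262; adjusted p = 0.705 with an estimated correlation). KLF2, a Krüppel-like transcription factor, rose from 0.768 ± 0.0794 to 5.34 ± 0.873 CPM and IER3 from 10.7 ± 0.817 to 24.1 ± 5.24 CPM, whereas the phosphatase DUSP2 fell from 4.5 ± 1.27 to 0.970 ± 0.191 CPM. FOS, FOSB and EGR1, the early response transcription factors, were also among the 5 lower members. FOS, with a log2 fold change of -1.09, had -0.47 without HEK293 replicate 1 and was not called (edgeR adjusted p = 0.106, 1.04e-12 to 0.106 over its alternatives). FOSB was not called without Synph-293 replicate 1 (edgeR adjusted p = 0.121), nor EGR1 without HEK293 replicate 1 (0.0546) or Synph-293 replicate 1 (0.211), and over the left-out libraries these ran from 1.29e-06 to 0.121 and from 1.51e-09 to 0.211. The list passed in 8 of 14 alternatives and was lost in limma on log2 TPM (camera adjusted p = 0.0996 and 0.0746), without HEK293 replicate 2 (0.179), Synph-293 replicate 1 (0.0557) and Synph-293 replicate 2 (0.0961; 0.0194 to 0.179 over the alternatives). Of 25 interferon-stimulated genes, 6 were higher and 2 lower, as also adjusted over the list alone (camera adjusted p = 0.318). BST2 rose from 33.0 ± 5.39 to 136 ± 2.94 CPM and IFITM1 from 8.74 ± 2.40 to 31.9 ± 3.15 CPM, while IFIT1 fell by 1.32 ± 0.24 on the log2 scale. With the median of neighbouring genes removed, the log2 fold change of IFITM1 went from 1.855 to 1.003 and that of BST2 from 2.042 to 1.817. Of 16 NF-kB and inflammatory genes, 5 were higher and 2 lower, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.0617), at low levels such as CCL2 with 0.485 ± 0.267 CPM in HEK293 and 3.26 ± 0.104 CPM in Synph-293. CCL2 had a log2 fold change of 2.78, or 3.42 without HEK293 replicate 2. The NF-kB list passed in 5 of 14 alternatives, among them those without a filter (camera adjusted p = 0.0340), without HEK293 replicate 1 (0.00860), without Synph-293 replicate 1 (0.00723) and with the median of neighbouring genes removed (0.0215; 0.00723 to 0.123 over the alternatives).

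**Figure D2:**
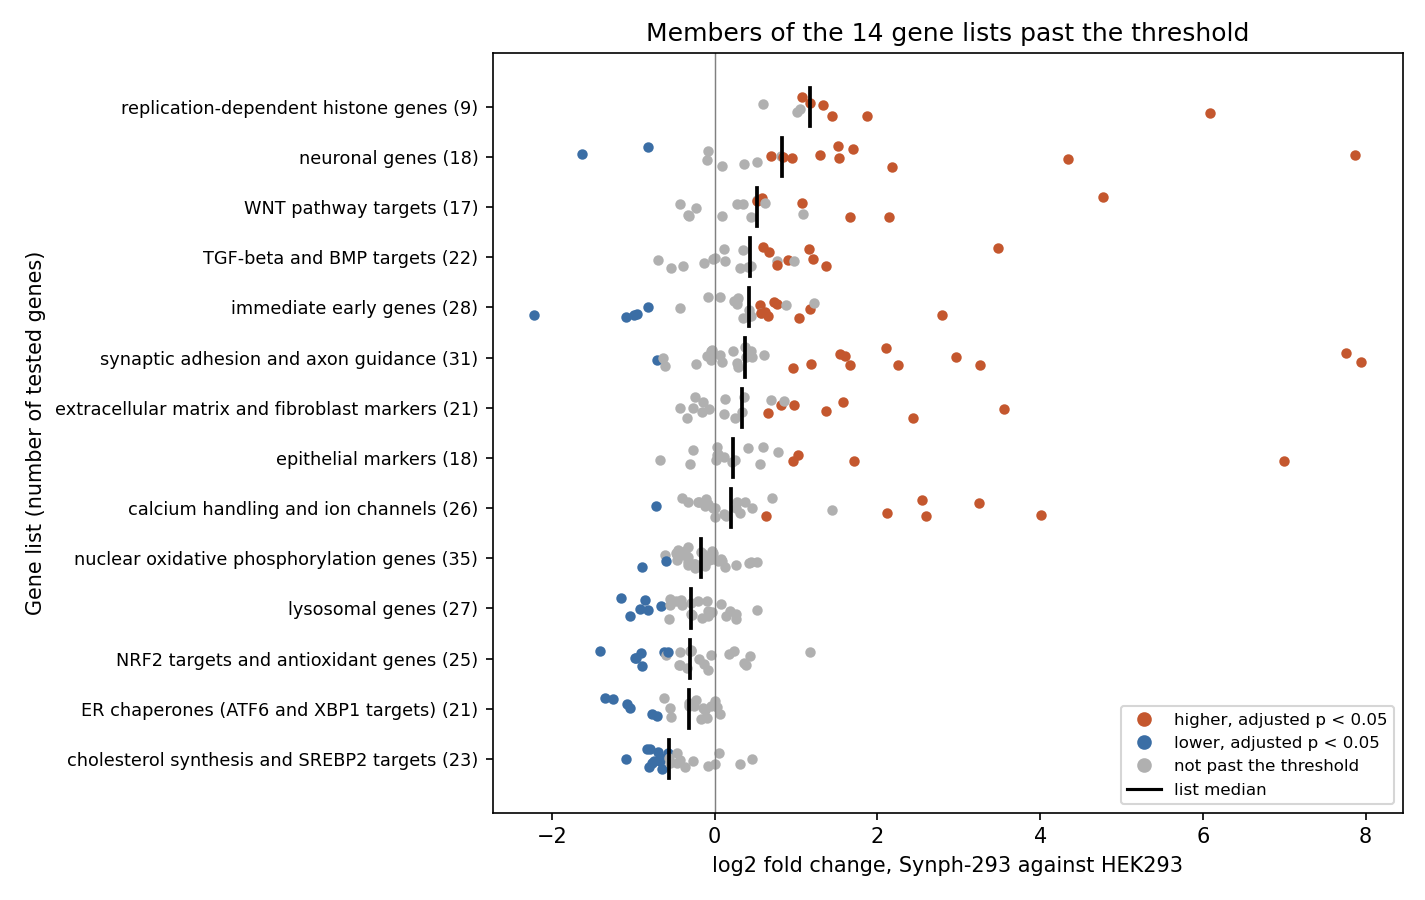
Log2 fold changes of Synph-293 against HEK293 (horizontal axis) for the tested members of the 14 lists past the threshold, 1 point per gene, coloured by call, with a line at each list median; fitted values of genes at 0 in a group have no exact size. Medians run from -0.56 for cholesterol synthesis to 1.17 for histone genes.

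Protein quality control lists other than the ER chaperones did not pass. Of 31 proteasome subunits, PSMD13 was higher and PSMA2 lower, as also adjusted over the list alone (camera adjusted p = 0.550). PSMA2 fell by 1.00 ± 0.17 and was not called without Synph-293 replicate 2 (edgeR adjusted p = 0.0637, 8.8e-16 to 0.0637 over its alternatives). PSMD13 had a log2 fold change of 0.69 ± 0.17 and was not called without Synph-293 replicate 1 (edgeR adjusted p = 0.223, 6.39e-08 to 0.642 over its alternatives), and its value was -0.16 with the median of its neighbours removed. Of 24 heat shock and cytosolic chaperone genes, HSPA1A was higher and 0 lower, as also adjusted over the list alone (camera adjusted p = 0.573), and its near-identical copy HSPA1B had a log2 fold change of 0.51 ± 0.20 that did not pass. HSPA1A was not called without Synph-293 replicate 1 (edgeR adjusted p = 0.158, 2.85e-06 to 0.158 over its alternatives). Of 25 autophagy genes, 3 were higher and 5 lower, as also adjusted over the list alone (camera adjusted p = 0.390). The kinase gene ULK2 fell from 8.63 ± 0.295 to 2.06 ± 0.128 CPM. On log2 TPM plus 1, ULK2 had a log2 fold change of -0.42 and did not pass (limma adjusted p = 0.433, 1.39e-15 to 0.433 over its alternatives). The autophagy receptor SQSTM1 fell by 0.64 ± 0.17 on the log2 scale and was not called without Synph-293 replicate 1 or 2 (edgeR adjusted p = 0.161 and 0.285, 1.04e-06 to 0.285 over its alternatives). Of 25 ATF4 targets, 2 were higher and 5 lower, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.151). ALDH1L2 fell from 72.2 ± 3.36 to 10.5 ± 0.731 CPM, and the stress cytokine GDF15 rose from 3.52 ± 1.06 to 10.2 ± 0.303 CPM.

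The p53, apoptosis, glycolysis and hypoxia, AMPK and mTOR, and ribosomal protein lists did not pass in the main fit either. Of 24 p53 targets, 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.434; 0.0292 with the median of neighbouring genes removed, 0.0292 to 0.822 over the alternatives). TIGAR was at 17.4 ± 4.54 CPM in HEK293 and 35.9 ± 1.85 CPM in Synph-293. Its call was lost in limma on log2 TPM (adjusted p up to 0.129, 9.21e-14 to 0.129 over its alternatives). Of 26 apoptosis regulators, 1 was higher and 3 lower, as also adjusted over the list alone (camera adjusted p = 0.235). PMAIP1 rose from 122 ± 2.71 to 227 ± 3.27 CPM and the inhibitor BIRC3 fell from 9.76 ± 1.62 to 3.42 ± 0.627 CPM. Of 25 glycolysis and hypoxia genes, the enolase ENO2, which is also in the neuronal list, was higher and BNIP3 lower, as also adjusted over the list alone (camera adjusted p = 0.573). ENO2 rose from 40.8 ± 0.268 to 100.4 ± 8.02 CPM, and BNIP3 was not called without Synph-293 replicate 2 (edgeR adjusted p = 0.192, 2.8e-07 to 0.192 over its alternatives). Of 25 AMPK and mTOR genes, 1 was higher and 3 lower, as also adjusted over the list alone (camera adjusted p = 0.215), and each of these 4 calls (CPT1A, TSC1, PRKAB2 and PRKAA2) was lost without Synph-293 replicate 1 (edgeR adjusted p from 0.181 to 0.276) and without Synph-293 replicate 2 (0.0593 to 0.350). PRKAB2 was also lost without HEK293 replicate 1 (0.104). Of 37 cytosolic ribosomal protein genes, RPS4X was higher and RPL30 lower, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.396). Both were lost without Synph-293 replicate 1 (edgeR adjusted p = 0.0766 and 0.226) and replicate 2 (0.225 and 0.251), and RPL30 had a log2 fold change of -0.66 that became 0.0296 with the median of its neighbours removed (over their alternatives, adjusted p ran from 1.28e-07 to 0.653 for RPS4X and from 1.27e-06 to 0.940 for RPL30).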

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

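The rise of SNCAIP passed in every alternative run, with log2 fold changes from 8.41 (limma on log2 TPM plus 1) to 10.47, and 10.22 to 10.47 with 1 library left out. Removing the median of neighbouring genes and crossing the replicate numbers were chosen after seeing the data, as was running the chromosomes under the alternatives. Another kind of count was not run, because the table held 1 kind. The deviations of same-numbered samples correlated at -0.28, which gave no sign that the numbers pair the samples but does not settle it. The mitochondrial share was 10.6% in HEK293 replicate 1 and 10.9% in Synph-293 replicate 2. It was 7.76% in HEK293 replicate 2 and 7.28% in Synph-293 replicate 1. A part of the spread within groups thus ran crosswise to the numbers. With the replicate block, 1380 genes were higher and 719 lower, 13 lists and 6 chromosomes passed, and SNCAIP had 10.35; 18 of the named genes and the oxidative phosphorylation, immediate early and epithelial lists lost their calls, while the NF-kB and the kidney and adrenal lists gained them. The crossed pairing gave 3251 higher and 3016 lower genes, and the epithelial and channel lists lost their calls. Against 1648 higher and 1081 lower (1067 and 338 at 2-fold), limma on log2 TPM plus 1 gave 1132 and 521 (578 and 179), on TPM plus 0.1 it gave 1086 and 474, glmTreat gave 736 and 190, and an adjusted p under 0.01 left 860 and 357. The DESeq2 Wald test gave 1310 and 917, and shared 2132 of the 2729 calls. An estimated correlation left 0 lists and 0 chromosomes, and without a filter 6 chromosomes passed. With the median of neighbours removed 565 genes were lower, and PSMD13 (-0.16), COX6C (0.0916) and RPL30 (0.0296) reversed, while 19 lists passed, the p53, fatty acid, NF-kB, kidney and adrenal, and HOX lists in addition to the 14 of the main fit. USP9X, SDHD, SCD, BNIP3, TSC1, PRKAB2, PRKAA2, FOS, CORO1A, RPS4X, RNF19A and NOTCH3 also lost their calls there. Leaving out 1 library gave 1049 to 2183 higher and 457 to 2042 lower genes, 885 to 1237 and 302 to 476 at 2-fold, 5 to 13 lists and 6 to 10 chromosomes, and 96 of the 140 named genes kept their call in all 4 fits. The 96 leave out SNCAIP, which also kept its call, and hold KRT5, which was not tested without Synph-293 replicate 2. Fewer libraries change both the spread and its estimate, and for all other shifts the cause was not tested. No named gene or called list reversed under the other alternatives. In the Synph-293 libraries 3 counts corresponded to 0.179 and 0.184 CPM, so the size of falls to lower levels was known only within wide limits.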

Other observations

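Of the tests below, those on other splits of the 4 libraries, on the nearest gene of genes without reads, on HEK293 replicate 1 by parts and on gene families were chosen only after the result was seen. The test on HEK293 replicate 1 was first written for the 3 lists together, of which 1 passed, and that did not decide, so it was divided.

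Some receptor and adhesion gene families, which the fixed lists covered in part or not at all, were higher in Synph-293. All 7 GABA-A receptor subunits tested were higher (edgeR, adjusted p under 0.05), with GABRQ going from 1.54 to 34.5 CPM, GABRE from 46.6 to 106 CPM and GABRA2 from 0 to 1.60 CPM, at least 7.94-fold higher. As a set they passed camera among 9 families with the preset correlation (adjusted p = 5.98e-09), also with the median of neighbouring genes removed (1.52e-09). However, GABRA2, GABRA4 and GABRB1 had 0 counts in both HEK293 libraries and entered the test only through Synph-293. The family was also chosen after the result was seen, so these p-values are no independent test. A median of 30 neighbours does not remove a shift shared by a few adjacent genes. With an estimated correlation 0 of the 9 families passed (adjusted p = 0.303 for this set, the lowest). Ephrin receptors had 5 of 13 members higher and 0 lower (camera adjusted p = 0.000218; 2.46e-05 with the median of neighbouring genes removed; adjusted p = 0.412 with an estimated correlation), with EPHB6 rising from 0.194 to 11.9 CPM and EPHA4 from 10.3 to 30.2 CPM. Cadherins had 5 of 12 higher and 0 lower (camera adjusted p = 0.0423; 0.00285 with the median of neighbouring genes removed; adjusted p = 0.412 with an estimated correlation). In the HEK293 libraries CDH4 had 0 and 0 counts, CDH13 0 and 2, CDH7 1 and 1, EPHA7 3 and 2 and EPHB6 4 and 2. These members too entered the test only through Synph-293. Both families were also chosen after the result was seen, so their p-values are no independent test. Of 45 clustered protocadherins, 28 were higher and 0 lower with a median log2 fold change of 1.19 (camera adjusted p = 4.05e-11; adjusted p = 0.357 with an estimated correlation). They lie side by side on chromosome 5 and share exons, so their counts are not independent. With the median of neighbours removed they did not pass (camera adjusted p = 0.562), but these neighbours are largely other members, so that does not test them.

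Other families were less uniform. Of 463 ZNF zinc finger genes, 41 were higher and 22 lower (camera adjusted p = 0.0186, upward, and adjusted p = 0.357 with an estimated correlation). With the median of neighbouring genes removed, the direction was downward and the set did not pass (camera adjusted p = 0.608). Of the 237 outside chromosome 19, 11 were higher and 18 lower (camera adjusted p = 0.909). Of 11 MAGE genes, 4 were higher and 1 lower (camera adjusted p = 0.0423; 0.612 with the median of neighbouring genes removed; adjusted p = 0.357 with an estimated correlation), and MAGED4B, which has a near-identical copy, went from 10.0 to 63.3 CPM. Of 10 Frizzled receptors, 2 were higher and 1 lower (camera adjusted p = 0.854), and of 255 solute carriers, 23 were higher and 21 lower (camera adjusted p = 0.681).

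Neighbouring genes shifted together along whole chromosome arms or long segments. On chromosome 7, from 0.136 to 44.8 Mb, 92.8% of 180 genes were lower in Synph-293, with a median log2 fold change of -0.51, and 71 were called lower against 2 higher. Chromosome 8 from 69.7 to 101 Mb (median -0.61), chromosome 9 from 33.0 to 89.0 Mb (-0.41) and chromosome 11 from 83.2 to 134 Mb (-0.49) were also lower, while chromosome 11 from 0.127 to 8.98 Mb (0.56) and chromosome X from 46.4 to 104 Mb (0.40) were higher. On chromosome 16 the 11 windows of 30 genes up to 31.9 Mb had medians from 0.15 to 0.36 and the 8 windows from 46.6 Mb had medians from -0.33 to -0.16. By camera 11 chromosomes passed an adjusted p of 0.05 with the preset correlation, upward 5, 19, 21, 22 and X and downward 2, 3, 7, 10, 14 and 18, and 0 passed with an estimated correlation (adjusted p = 0.0840 at the lowest).

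A candidate explanation for these blocks is that the lines differ in gains and losses of chromosome segments, which HEK293 sublines can carry. It predicts that 2 disjoint sets of genes from 1 window shift alike, and over 402 windows of 30 neighbouring genes the medians of such sets correlated at 0.890 across windows, against at most 0.156 in 1000 random gene orders. Any cause that moves neighbours together predicts this too, so the value does not single out gains and losses of segments. Variation between libraries of a group is argued against as the whole cause, as the same correlation reached 0.278 between the HEK293 and 0.365 between the Synph-293 replicates. Both values lie above the 0.156 of random gene orders, which were run on the comparison of the groups only. A part played by such variation is therefore not excluded. A bias by GC content or transcript length is argued against as well, as the correlation between the groups stayed at 0.863 with that trend removed. With the median of neighbours removed, 1239 genes were higher and 565 lower, and 1557 of the 2729 calls were shared. Copy number was not measured here, and regional changes of transcription would give the same blocks.

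Genes without a read in 1 line and with at least 20 counts in both libraries of the other numbered 32, of which 27 were silent in HEK293 (LINC00305, ZNF334 and CDH4 among them) and 5 in Synph-293 (ZNF835, ZNF257 and IQCA1 among them). Too few reads would give such genes for any split of the libraries, and the other 2 ways to part the 4 libraries into pairs gave at most 3 such genes, against 32 for the real groups. The test written before the result, on single libraries, did not decide and was replaced by this one, with up to 13 such genes between libraries of a group and at least 61 between libraries of different groups. A loss of the whole region in all copies would take the neighbours too, but the nearest tested gene was also without a read for only 9.38% of them. A candidate explanation that stays open and was not tested is stable silencing or activation of single genes in cells that went through a selection step, and an effect of synphilin-1 itself is not excluded.

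The lower levels of ER chaperone, lysosomal and cholesterol synthesis genes could reflect regional shifts along the chromosomes or HEK293 replicate 1 alone. With the median of neighbouring genes removed, 3 of the 3 lists still passed downward, which argues against regional shifts as the whole cause. Without HEK293 replicate 1 the cholesterol list, as 1 list of 1, still passed downward by camera, with a median of -0.56 before and -0.38 after. The rule for this list was written after that outcome was seen, so it does not decide whether HEK293 replicate 1 alone set the fall. For the other lists, 0 of 2 passed without HEK293 replicate 1. The ER chaperone median went from -0.32 to -0.05 and the lysosomal median from -0.29 to -0.14. For the 3 lists, HEK293 replicate 1 and a difference between the lines cannot be told apart with the 1 HEK293 library that remains. A biological effect of synphilin-1 on these lists stays open and was not tested.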
